A study of Caenorhabditis elegans with 2 samples.

How the data were processed

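The data are peak lists from ChIP-seq of the eGFP-tagged C34F6.9 product in whole L2 larvae of C. elegans, with 2 biological replicates, per the labels. The tagged gene was carried as a transgene in an unc-119 mutant background, per the labels. The deposited lists are in narrowPeak format for the ce11 and ce10 builds. Per the deposited listing of the files, the list of each replicate was called on that replicate's alignments with a control library, the pooled list on both replicates together, and the optimal list by IDR thresholding of the pooled list with the lists of both replicates. The control library itself was not analysed here. The aligner, the peak caller, their versions and the treatment of reads that match several places are not given in the sources used here.

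The signal of each deposited peak is the authors' own value, made relative to a control and on no scale shared between lists, so it was used only to describe, rank and filter peaks within a list. The deposited −log10 q-values reach a ceiling of 4.07 in the optimal list, which all 5692 of its peaks hold, so they carried no ranking and were used only for that check. The summit is the deposited offset from the start of the peak. The optimal list was found to be exactly the 5692 pooled peaks with the highest signal. In that list 74.1% of the peaks have the same width of 396 bp, and the peaks overlap into 5531 separate regions. The lists hold no read counts, so depth is unknown and no interval on a peak's signal can be given. Intervals on shares of genes are 95% Wilson intervals and, with odds ratios, exact ones, and cover counting error only.

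Positions are 1-based in ce11, whose chromosome lengths match the WBcel235 assembly. Genes, transcripts and biotypes came from Ensembl annotation release 115, and sequence from the RefSeq copy of the same assembly. The ce10 lists were used for the number of peaks and the X share only, with no conversion of coordinates. A gene was called bound where an optimal summit lay within 500 bp of the 5′ end of any of its transcripts, and all 19973 protein-coding genes were the background of the gene list tests. Genes with more annotated 5′ ends had more chances to be called bound, and no test adjusted for their number. Classes of location were assigned in the order promoter, exon, intron, within 500 bp after a 3′ end, and intergenic. Chance placement came from 1000 circular shifts of the summits within each chromosome, with permutation p. Counts of genes were compared by Fisher's exact test, two-sided. Signal percentiles were compared by a permutation test with 100000 resamples. Benjamini-Hochberg adjustment was made over the 30 lists, the 10 gene classes with at least 20 genes, the 5 location classes and the 2080 6-mers, with a threshold of 0.05. For 6-mers, a summit counted once if the sequence within 50 bp of it held the 6-mer on either strand, against windows of the same length 300 bp to either side. Both flanks of a summit were counted as separate windows, and their pairing with the centre was not used. Some peaks also overlap, so the windows are not independent and the p-values for 6-mers are approximate.

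The 2 replicates form 1 group, so nothing was compared between groups. Values from each replicate alone used its 5692 highest-signal peaks, and these also served as the alternatives that leave out the other replicate. Both replicates come from the same strain, and their spread includes culture and technical differences together.

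The gene lists, the main tests and the alternatives were fixed before the data were examined, except for the ce10 count, the shuffled background for 6-mers and the comparisons stated to be later. The genes named were, by rule, the coding gene with the nearest 5′ end within 500 bp of each of the 20 peaks with the highest signal, all genes within 500 bp of the 10 highest, up to 4 members with the strongest peak of each list past the threshold and up to 2 of each other list, together with C34F6.9 and unc-119. Genes named near peaks without a coding 5′ end within 500 bp, the further genes at shared promoters below the 10 highest, the non-coding genes and the 6-mers were chosen after the data were seen. One heterochronic and one coelomocyte or excretory list member were not found in the annotation under the names used, so 21 and 15 were tested. The alternatives were windows of 250 and 1000 bp, nearest 5′ end only, the 2846 peaks with the highest signal, genes with any pooled region as background, all annotated 5′ ends, uniform placement, other matching distances, other windows for 6-mers, chromosome length as background, each replicate alone and, chosen after the data were seen, the ce10 count and shuffled centres as the 6-mer background. Stratified odds ratios in the closing observations are Mantel-Haenszel estimates. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

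The procedures were tested on simulated data. With random summits, 1 of 2080 6-mers passed the threshold, and a 6-mer planted in 10% of centres had the smallest p of all. Of 500 simulated lists with raised odds of a peak, 87.2% were recovered, and 0.56% of 2500 other lists were called. The raised lists were repeats of the ribosomal protein, respiratory chain, cell cycle, homeobox and histone lists, of 43 to 96 genes. All had the same rise in odds, so the share recovered does not cover shorter lists or smaller rises. Peaks were drawn there for each gene independently, so these rates do not cover real lists whose genes share a peak. Of 100 random summit sets, 4% gave a permutation p under 0.05 for the promoter share.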

Results

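Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the eGFP-tagged product of C34F6.9 lay on the genome of Caenorhabditis elegans. The material was whole larvae of the second larval stage (L2), of pooled sex, from a strain that carries the tagged gene as a transgene with an unc-119 rescue marker. There was 1 group with 2 replicates, which the labels describe as biological, so the question was where the peaks lay and not how they changed. The peak lists carry no read counts, so the depth of each library is unknown. The optimal list, made by the authors with an irreproducible discovery rate (IDR) threshold, held 5692 peaks in the ce11 build. These were exactly the pooled peaks with the highest signal, so a place in the list need not mean that a peak was found in each replicate. Each replicate and the pool of both also had a list of 30000 peaks and background regions. All positions below are in ce11.

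Most peaks lay at the same places in both replicates. Of the 5692 highest-signal peaks of replicate 1, 4270 (75.02%) had a summit of the 5692 highest of replicate 2 within 100 bp. Shifted lists gave 1.19% on average and 1.65% at most (permutation p = 0.000999, one-sided, the smallest that 1000 shifts can give). The optimal list was made with an IDR threshold, but its members are exactly the pooled peaks with the highest signal. The pooled list was called on both replicates together, so the match and the correlation below are not independent of it. Of the optimal peaks, 5372 (94.4%) had a match within 100 bp in the full lists of both replicates, and 2 had a match in neither. The full lists include background regions, and no shifted level was computed for this share. For 4288 optimal peaks (75.3%) the match was among the 5692 highest-signal peaks of each replicate. The 5372 peaks with a match in both full lists are not independent replicates. Across them the authors' signal values gave a Spearman rho of 0.797 and a Pearson r of 0.807 on the log2 scale. The summits of a matched peak lay a median of 24 bp apart. The signal is the authors' own value per peak and is used here only to rank peaks within a list.

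Peaks were more frequent near the 5′ ends of protein-coding genes, and rarer in exons, than shifted summits. A summit within 500 bp of an annotated 5′ end of a protein-coding transcript was found for 2887 of 5692 peaks (50.7%), against 22.8% for shifted summits (95% of shifts between 21.6% and 23.9%). That was a 2.23-fold excess (permutation p = 0.002, two-sided, the smallest that 1000 shifts can give). The highest-ranked peaks of the single replicates gave 50.4% ± 0.981 (SD, n = 2), and the 24308 pooled regions outside the optimal list gave 24.1%. Of the 2887 promoter-proximal summits, 88.2% were upstream of the 5′ end, at a median of -150 bp with quartiles of -250 and -65 bp. Outside that window, exons held 81 summits (1.42% of all, against 21.04% for shifted summits) and introns 900 (15.8%, against 27.1%). Intergenic sequence held 1557 summits (27.4%, against 25.08%), and the 500 bp after a 3′ end held 267 (4.69%, against 4.05%). All 5 classes differed from the shifts, with Benjamini-Hochberg adjusted permutation p of 0.0025 for the first 4 and 0.022 for the last. Many genes of this animal are trans-spliced, so an annotated 5′ end need not be the place where transcription starts.

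**Figure D1:**
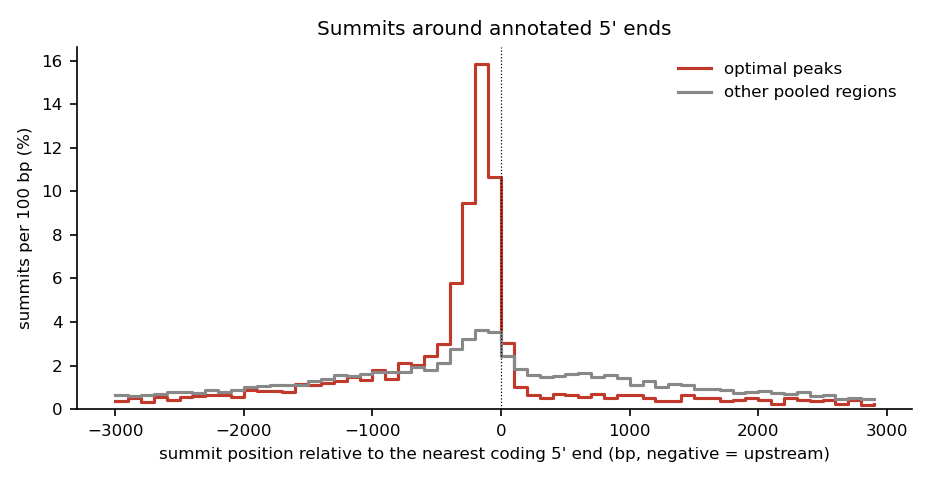
Position of each summit relative to the nearest protein-coding 5′ end (x axis, bp, negative upstream) as the share of summits per 100 bp (y axis, %), for the 5692 optimal peaks and the 24308 other pooled regions. The optimal peaks gather upstream of the 5′ end, with a median of -150 bp among those within 500 bp.

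Peaks with higher signal lay at promoters more often. The promoter-proximal share was 68.2% in the highest of 10 equal groups of peaks by signal and 33.9% in the lowest. The median signal percentile was 60.1 for promoter-proximal peaks and 39.7 for the others, a difference of 20.5 (permutation p = 1e-05, two-sided, the smallest that 100000 resamples can give).

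**Figure D2:**
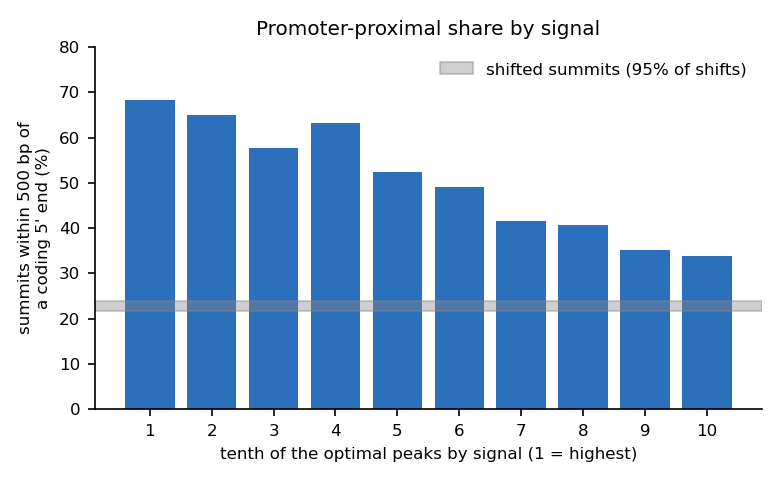
Share of summits within 500 bp of a protein-coding 5′ end (y axis, %) in 10 equal groups of the 5692 optimal peaks, from highest to lowest signal (x axis). Bars fall from 68.2% in the first group to 33.9% in the last, and the grey band spans 21.6% to 23.9%, the range of 95% of shifts of all 5692 summits. That range was already 21.3% to 24.35% for the 2846 strongest peaks, so the band is too narrow for single groups.

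The strongest peaks included those at cdc-48.1, at rpl-3 and between Y17G9B.5 and rpl-20. The highest signal (1188.65) belonged to the peak at II:10563385-10563761, whose summit lay 152 bp from a 5′ end of cdc-48.1 (WBGene00007352), which encodes an ATPase that extracts ubiquitinated proteins. It ranked 1 in both replicates, and the snoRNA gene C06A1.9 also had its 5′ end within 500 bp of the summit. Next among promoter peaks were rpl-3 (WBGene00004414, summit III:3867581, 273 bp, signal 1060.94), a ribosomal protein gene, and the divergent pair Y17G9B.5 (WBGene00021202) and rpl-20 (WBGene00004432) around IV:4750065 (signal 1045.46). The peak of rank 5 lay 35 bp from a 5′ end of tasp-1 (WBGene00010480, III:10759272). Ranks 8 and 9 were the histone gene his-37 (V:9547003, 102 bp) and iff-2, a translation factor gene (II:8561441, 74 bp). The histone genes are near-identical copies and the authors' treatment of reads that match several copies is not given in the sources used here, so the place of the his-37 peak within its family is uncertain. Rank 11 lay 387 bp from eef-1A.2 (X:7823267), and rank 20 lay between eef-1A.1 and rfc-4 (III:6972093); the eef-1A genes encode elongation factor 1 alpha. Ranks 12 and 19 were at rpl-35 (III:7854675, 459 bp) and at rpl-15 with K11H12.8 (IV:654930). Ranks 15 to 18 were at eelo-2 (IV:17249899), at set-16 with drr-2 (III:13643751), at sec-61.G (V:10897365) and at cox-5A (III:12905206). The set-16 gene encodes a histone methyltransferase, sec-61.G a subunit of the protein translocation channel and cox-5A a subunit of cytochrome c oxidase.

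Of the 20 highest peaks, 6 had no protein-coding 5′ end within 500 bp. Rank 2 (II:8787389-8787793, signal 1086.33) was intergenic, 2959 bp from the 5′ end of F07H5.13 and within 500 bp of the pseudogene WBGene00014309. Rank 6 (III:9765418-9765891) was intergenic, 871 bp from the 5′ end of cbp-1, a histone acetyltransferase gene. Ranks 7 and 10 were intergenic on X, at summits 16929714, near the ncRNA gene C30E1.9, and 11094177. Rank 13 (II:5844595-5845109) lay at sls-2.1, a gene for the SL2 spliced leader RNA, and rank 14 (III:3801301-3801803) lay 1099 bp from a 5′ end of mtm-3.

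Genes of the basic cell machinery had peaks far more often than other genes. Of 19973 protein-coding genes, 3400 (17.02%) had an optimal summit within 500 bp of a 5′ end. Of the 30 gene lists fixed before the data were examined, 19 differed from all other coding genes at an adjusted p under 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg over the 30 lists), 10 with more peaks and 9 with fewer. Among ribosomal protein genes, 65 of 76 had a peak (85.5%, 95% Wilson interval 75.9% to 91.7%). The odds ratio was 29.3 (15.3 to 61.7) with an adjusted exact p of 7.38e-38. Of the alternatives run, only the 250 bp window ended that call, with an odds ratio of 1.86 and an adjusted exact p of 0.0728. The odds ratio was 52.5 within 1000 bp, 7.86 with the nearest 5′ end only and 15.4 among the 7368 genes with any pooled region near a 5′ end. The proteasome, the complex that degrades ubiquitinated proteins, had peaks at 28 of 33 genes (84.8%, odds ratio 27.5, adjusted exact p = 2.61e-16). Its 4 highest were rpn-3 (III:8447164, signal 731.57, rank 27), rpn-9 (II:11239182, rank 294), rpt-2 (V:6017810, rank 344) and pbs-2 (I:12968620, rank 370). Its odds ratio fell to 8.57 with the nearest 5′ end only, 7.14 within 250 bp and 6.58 among genes with any pooled region, each still past the threshold. The respiratory chain had 32 of 46 (69.6%, odds ratio 11.2, adjusted exact p = 3.23e-14), led by cox-5A (rank 18), cox-6B (III:2786055, rank 42), atp-1 (I:12652266, rank 80) and cox-5B (I:9788699, signal 520.51). Its odds ratio was 5.79 with the nearest 5′ end only and 6.97 within 250 bp, also past it.

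Peaks were also more frequent at genes for translation, splicing, folding and the cell cycle. Cell cycle genes had 25 of 43 (58.1%, odds ratio 6.81, adjusted exact p = 5.22e-09), among them cdk-7 (I:2291235, rank 72), pcn-1 (IV:4049719, rank 120), lin-35, the retinoblastoma homologue (I:5807495, rank 171), and cdc-6 (I:4270562, rank 187). Heat shock and chaperone genes had 32 of 60 (53.3%, odds ratio 5.61, adjusted exact p = 7.67e-10), led by hsp-110, whose peak was the one at rpn-3, then cct-1 (II:8185200, rank 43), hsp-90 (V:14685779, rank 51) and cct-7 (V:1871922, rank 131). Aminoacyl-tRNA synthetases, the enzymes that charge tRNAs, had 17 of 32 (53.1%, odds ratio 5.55, adjusted exact p = 9.33e-06), with kars-1 (II:7072759, rank 261), mars-1 (IV:11635826, rank 405), nars-1 (I:7090377, rank 1108) and aars-1 (II:11464671, rank 1358). Restricted to the 2846 peaks with the highest signal, this list gave an odds ratio of 1.85 with an adjusted exact p of 0.22, and in replicate 2 alone 3.43 with an adjusted exact p of 0.00196. Splicing factors had 24 of 47 (51.1%, odds ratio 5.12, adjusted exact p = 3.03e-07), led by prp-40 (III:9521896, rank 110), rsp-2 (II:11453197, rank 204), prp-8 (III:8164082, rank 216) and snrp-3 (IV:8687968, rank 236). Chromatin and synMuv genes had 17 of 43 (39.5%, odds ratio 3.198, adjusted exact p = 0.000721), led by set-16 (rank 16), lin-54 (IV:13240683, rank 56), lin-53 (I:9620009, rank 109) and lin-9 (III:8904298, rank 152). With the nearest 5′ end only, the odds ratios fell to 3.74 for cell cycle genes, 3.16 for chaperones and 3.25 for splicing factors. Among genes with any pooled region they were 4.19 for cell cycle genes and 3.13 for chaperones, and all 5 values were past the threshold.

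Markers of 2 tissues were also bound more often. Pan-neuronal markers had 18 of 36 (50%, odds ratio 4.90, adjusted exact p = 1.26e-05), led by unc-76 (V:15071438, rank 260), ric-3 (IV:7818045, rank 432), rgef-1 (V:9562007, rank 551) and egl-21 (IV:10481912, rank 662). Body wall muscle markers had 14 of 39 (35.9%, odds ratio 2.74, adjusted exact p = 0.00712), led by act-2 (V:11078577, rank 675), unc-112 (V:14697028, rank 840), act-4 (X:4962503, rank 1716) and pat-6 (IV:264542, rank 2112). Among the 7368 genes with any pooled region near a 5′ end, neither list differed from the rest, with odds ratios of 1.40 (adjusted exact p = 0.547) and 0.961 (adjusted exact p = 1). The muscle odds ratio was 4.77 in replicate 2 alone (adjusted exact p = 8.85e-06) and 2.16 in replicate 1 alone (adjusted exact p = 0.0527). Its call was also lost within 250 bp (2.27, adjusted exact p = 0.0682) and in the 2846 strongest peaks (1.75, adjusted exact p = 0.255).

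**Figure D3:**
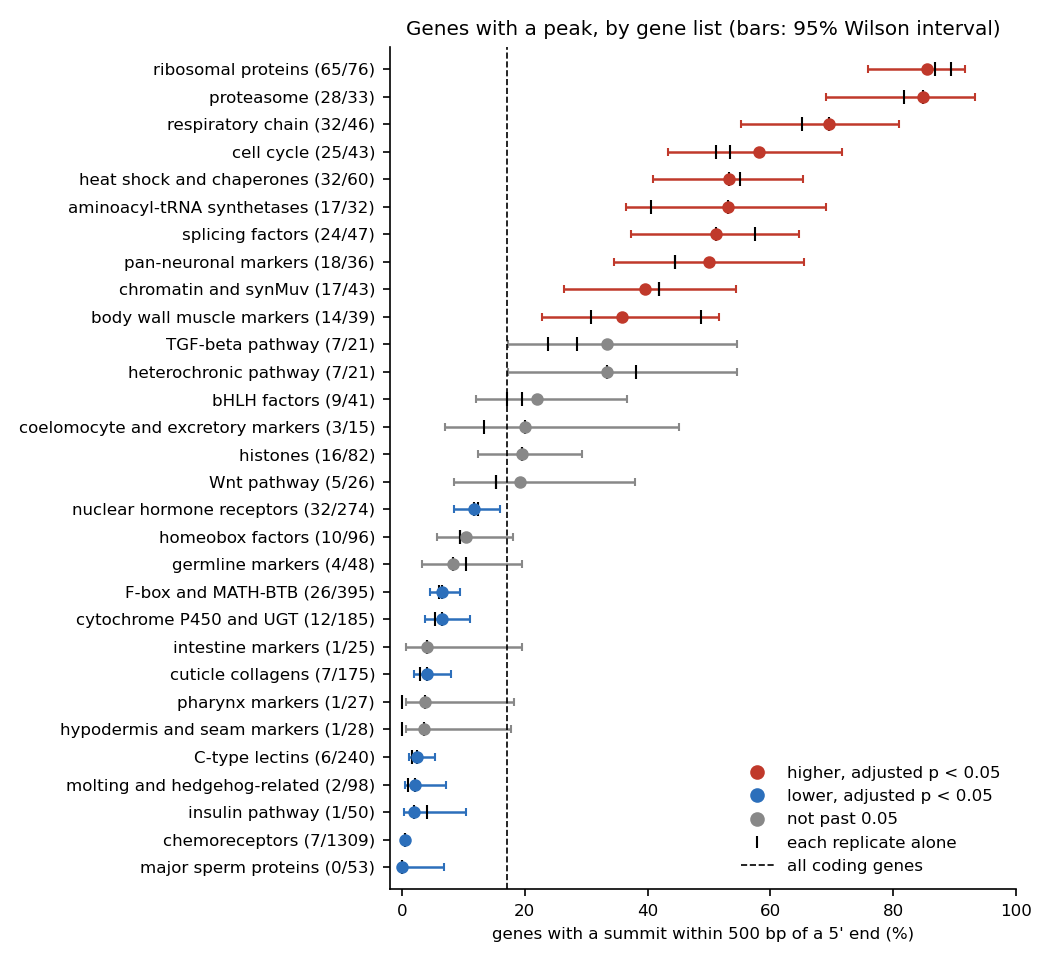
Share of genes with an optimal summit within 500 bp of a 5′ end (x axis, %) for each of the 30 gene lists (y axis, genes with a peak over genes in the list). Points carry 95% Wilson intervals, ticks show each replicate alone, the dashed line marks all coding genes (17.02%), and colours mark lists with more, fewer or neither at adjusted p under 0.05; ribosomal proteins (85.5%) and chemoreceptors (0.535%) lie near the ends.

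Chemoreceptor, lectin, collagen and detoxification enzyme genes were among the 9 lists with fewer peaks. Chemoreceptor genes had 7 of 1309 (0.535%, odds ratio 0.0242, adjusted exact p = 1.93e-95), the highest being sri-5 (I:11182538, rank 337), srh-16 (V:12291802, rank 495), str-12 (V:15610541, rank 2129) and srh-2 (V:731486, rank 2832). Major sperm protein genes had 0 of 53, which allows a share of up to 5.66% (3 counts of the total, with the Wilson interval reaching 6.76%; odds ratio 0, adjusted exact p = 0.000146). C-type lectins had 6 of 240 (2.5%, odds ratio 0.123, adjusted exact p = 6.68e-12), led by clec-140 (II:4672843, rank 1145), and cuticle collagens had 7 of 175 (4%, odds ratio 0.201, adjusted exact p = 4.73e-07), led by col-38 (II:8569524, rank 142) and col-71 (II:3502858, rank 500). Molting and hedgehog-related genes had 2 of 98 (odds ratio 0.10, adjusted exact p = 1.17e-05), wrt-3 (rank 3655) and grl-26 (rank 3885). Genes for cytochrome P450, UDP-glucuronosyltransferase and glutathione S-transferase enzymes had 12 of 185 (6.49%, odds ratio 0.336, adjusted exact p = 6.60e-05), led by gst-27 (II:15166086, rank 958), gst-43 and gst-24. F-box and MATH-BTB genes had 26 of 395 (6.58%, odds ratio 0.338, adjusted exact p = 4.71e-09), led by fbxb-85 (III:10849035, rank 189). Insulin pathway genes had 1 of 50, which was daf-16 (I:10750060, rank 2270; odds ratio 0.0992, adjusted exact p = 0.00347). Nuclear hormone receptors had 32 of 274 (11.7%, odds ratio 0.641, adjusted exact p = 0.0293), led by nhr-47 (V:5505227, rank 215) and nhr-49 (I:9869284, rank 373). Among the 7368 genes with any pooled region, the collagen, lectin, F-box and sperm protein lists no longer differed (odds ratios 0.453, 0.778, 1.05 and 0). The insulin call was lost within 1000 bp (0.403, adjusted exact p = 0.0733) and in the 2846 strongest peaks (0.163, adjusted exact p = 0.0622). The nuclear hormone receptor call was lost within 250 bp (adjusted exact p = 0.0651), with the nearest 5′ end only (adjusted exact p = 0.281) and in replicate 1 alone (adjusted exact p = 0.0643). Calls that held moved by over 1.5 times for several lists. The chemoreceptor odds ratio ranged from 0.0161 within 250 bp to 0.0752 among genes with any pooled region, and the molting list from 0 in the 2846 strongest peaks to 0.156 within 250 bp. The lectin odds ratio was 0.0626 within 250 bp and 0.0812 in replicate 1 alone, and the collagen one 0 within 250 bp and 0.1085 with the nearest 5′ end only. The insulin odds ratio was 0.208 in replicate 2 alone. In the 2846 strongest peaks the detoxification list gave 0.131 and nuclear hormone receptors 0.395, with 0.392 for the latter among genes with any pooled region.

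The other 11 lists did not pass the threshold. Heterochronic genes, which time larval development, had 7 of 21 (33.3%, odds ratio 2.44, adjusted exact p = 0.0961), including lin-28 (I:8409904, rank 308) and lin-66 (IV:13887735, rank 962). The TGF-beta pathway also had 7 of 21, including daf-1 (IV:132265, rank 2492) and sma-3 (III:6864123, rank 2968). Both passed with each peak given to its nearest 5′ end only (odds ratio 3.14, adjusted exact p = 0.0275) and within 1000 bp (4.86 for heterochronic genes and 3.31 for TGF-beta), and the heterochronic list passed in replicate 2 alone (3.08, adjusted exact p = 0.023). In replicate 2 alone the TGF-beta odds ratio was 1.56 (adjusted exact p = 0.436), and the heterochronic one was 1.26 within 250 bp. Histone genes had 16 of 82 (19.5%, odds ratio 1.18, adjusted exact p = 0.595), including his-37 and htz-1 (IV:4445916, rank 125), but among genes with any pooled region the odds ratio was 4.69 (adjusted exact p = 0.00826). Basic helix-loop-helix factors had 9 of 41, the Wnt pathway 5 of 26 and coelomocyte and excretory markers 3 of 15, with adjusted exact p of 0.449, 0.793 and 0.756. Homeobox factors had 10 of 96 (10.4%, adjusted exact p = 0.126), led by ceh-38 (II:6951574, rank 50), and germline markers 4 of 48 (8.33%, adjusted exact p = 0.144). Intestine markers had 1 of 25 (erm-1, rank 1962), pharynx markers 1 of 27 (peb-1, rank 5449) and hypodermis and seam markers 1 of 28 (rnt-1, rank 5221), with adjusted exact p of 0.129, 0.0961 and 0.0961. The pharynx and hypodermis lists had 0 members in replicate 2 alone and passed there, with adjusted exact p of 0.023 and 0.0161. The intestine and pharynx lists passed within 1000 bp (odds ratios 0.151 and 0.14), and the hypodermis list among genes with any pooled region (0.116, adjusted exact p = 0.0285).

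Genes in a head-to-head arrangement had peaks more often than other genes. Of 3729 genes with an opposite-strand coding 5′ end within 1000 bp upstream, 1499 (40.2%) had a peak, against 1901 of 16244 other genes (11.7%; odds ratio 5.07, 95% interval 4.67 to 5.50, Fisher's exact test, two-sided, with p at the limit of double precision). A single summit can serve both genes of such a pair. With each peak given to its nearest 5′ end only, the odds ratio was 2.35 (2.14 to 2.57, Fisher's exact p = 5.19e-72).

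Several classes of non-coding RNA genes also carried peaks. Of 612 tRNA genes, 202 (33.01%) had a summit within 500 bp of the 5′ end, against 5.55% for shifted summits, and of 346 snoRNA genes 113 (32.7%), against 5.66%. Excesses of 2.72, 2.67, 2.37 and 2.25 times the shifted share were found for snRNA, ncRNA, lincRNA and miRNA genes. The piRNA genes (322 of 15363, 0.427 times) and pseudogenes (43 of 2128, 0.405 times) had fewer peaks than shifted summits. Each of these 8 classes had an adjusted permutation p of 0.0025 (two-sided, Benjamini-Hochberg over 10 classes), the smallest the shifts gave after adjustment. The tRNA excess of 5.95 times was 10.4 within 250 bp and 3.66 in the 2846 strongest peaks, where that of snRNA genes was 4.26. Within 250 bp the excess was 9.27 for snoRNA, 4.41 for snRNA and 4.15 for ncRNA genes, and piRNA genes had 0.241 times the shifted share. The miRNA call was lost within 250 bp (1.90 times, adjusted permutation p = 0.0549). Antisense RNA genes (7 of 100) and rRNA genes (0 of 20, with 4.59% for shifted summits) did not differ, with adjusted p of 0.564 and 0.925. Reads from tRNA and rRNA copies can match several places, which the peak lists cannot resolve. No ChIP of an untagged strain was analysed here, so non-coding genes that enrich in any ChIP experiment cannot be told apart from sites of the tagged product. Over 1000 bp from every coding 5′ end, 121 of 387 tRNA genes (31.3%) and 48 of 193 snoRNA genes (24.9%) had a peak, a comparison without a test that was chosen after the data were seen. There snRNA genes had 3 of 68 (4.41%), against 13.95% of all snRNA genes and 5.12% of them for shifted summits, and lincRNA genes had 11 of 132 (8.33%). The highest-ranked examples, also chosen after the data were seen, were the tRNA genes WBGene00022939 (X:8036685-8036757, rank 167) and WBGene00014564 (II:12678314-12678385, rank 254), and the snoRNA genes C06A1.9 (rank 1) and F54E7.10 (III:5679378-5679509, rank 30). Among miRNA genes, cel-mir-5549 shared the rank 20 peak with rfc-4 and eef-1A.1.

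Peaks were spread unevenly over the chromosomes. Chromosome III had 74.7 optimal peaks per Mb, I 71.5, II 59.3, X 55.1, IV 50.7 and V 38.95. X held 977 of the 5692 optimal peaks (17.2%) but 5597 of the 24308 other pooled regions (23.03%; odds ratio 0.693, 95% interval 0.642 to 0.747, Fisher's exact p = 8.99e-23, two-sided). Against chromosome length, of which X makes up 17.7%, the share did not differ (odds ratio 0.965, exact binomial p = 0.322). Of the coding genes on X, 378 of 2731 (13.8%) had a peak, against 3022 of 17242 (17.5%) on the autosomes (odds ratio 0.756, Fisher's exact p = 1.21e-06). On the autosomes, 2155 of 4715 optimal peaks (45.7%) lay in the central part of equal length to each arm, against 39.01% of the other regions (odds ratio 1.32, 1.23 to 1.40, Fisher's exact p = 8.29e-17).

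The sequence under the summits was rich in short GA 6-mers such as GAGAGA and in an ACGCAG-containing element. Longer GA runs, of 10 bp or more, were found in the centre or flanks of only 290 summits (5.09%). Of the 2080 possible 6-mers, each counted with its reverse complement, 1536 differed between the sequence within 50 bp of each optimal summit and windows of the same length 300 bp to either side (Fisher's exact test, adjusted p under 0.05), 848 more frequent in the centre and 688 less. GAGAGA was present in 31.2% of centres and 6.11% of flanks (odds ratio 6.96), and AGAGAG in 26.7% and 4.80% (7.21). Their p-values were smaller than double precision can hold. ACGCAG had the highest odds ratio of the 12 leading 6-mers, with 16.8% and 1.87% (odds ratio 10.6, adjusted exact p = 1.77e-272). The overlapping 6-mers GACGCA (odds ratio 9.75), AGACGC (8.06), CGTCTC (7.93), CGCAGA (6.78) and AGAGAC (6.63) were also among the 12, as were AAGAGA (4.13), AGAGAA (3.59), CGAGAG (5.30) and GAGCGC (7.50, and 4.76 with windows reaching 100 bp to either side). Among the less frequent 6-mers, AAAATT was in 19.4% of centres and 43.9% of flanks, TTAAAA in 9.59% and 29.4%, and AAAAAT in 27.2% and 50.98%. GC content was 43.95% ± 7.97 (SD over 5692 windows) in centres and 34.8% ± 8.31 in flanks, with 35.4% in the whole genome. The named 6-mers are the 12 more and 3 less frequent ones with the smallest p, a rule set after the data were seen. Against centres shuffled with their dinucleotide counts kept, a background added after the data were seen, 420 of the 1204 6-mers past the threshold were more frequent (34.9%, against 55.2% with flanks). The 12 leading 6-mers were past the threshold there too, but with lower odds ratios, between 1.97 (AAGAGA) and 4.69 (ACGCAG), with 2.55 for GAGAGA and 2.25 for AGAGAG. There AAAATT no longer differed (odds ratio 1.09, adjusted exact p = 0.104), AAAAAT turned to 1.42 (adjusted exact p = 2.32e-14) and TTAAAA had 0.813.

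**Figure D4:**
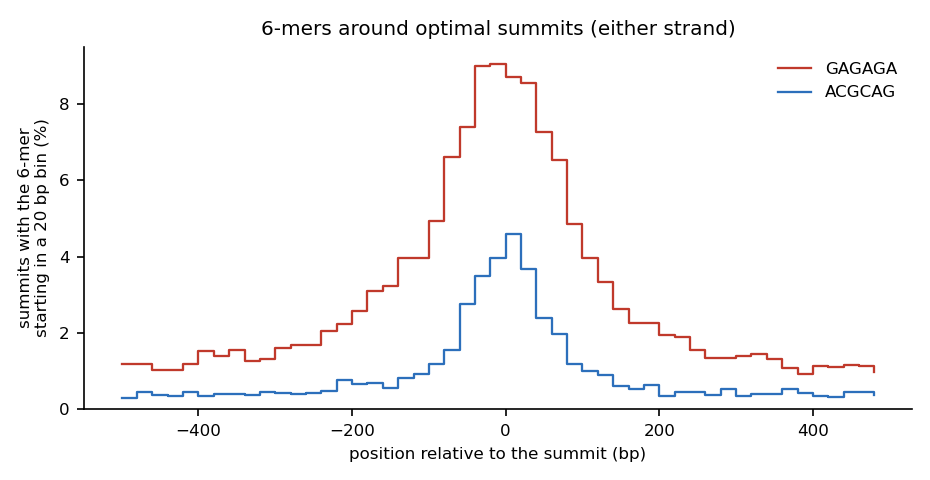
Share of the 5692 optimal summits with GAGAGA or ACGCAG, on either strand, starting in each 20 bp bin (y axis, %) by position relative to the summit (x axis, bp). Both gather at the summit, where GAGAGA reaches 9.07% and ACGCAG 4.60% of summits per bin.

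The native locus of the tagged gene carried no peak. No optimal peak lay in C34F6.9 (WBGene00007943, X:11218128-11222647, minus strand), and 1 lay within 20 kb of it, with its summit at X:11241679 (rank 2531, signal 124.28; rank 3063 in replicate 1 and 1986 in replicate 2). The rescue marker gene unc-119 (WBGene00006843, III:10902641-10908935, plus strand) held 3 optimal peaks, with summits at 10905387 (rank 1390), 10903319 (rank 2069) and 10906530 (rank 4731). Among the 5692 highest peaks of single replicates it held 2 in replicate 1 and 4 in replicate 2. The peak lists do not separate reads of the native gene from reads of the marker copies, and the part of unc-119 in the marker is not given in the sources used here. Of 1514 coding genes within 20% of its length of 6295 bp, 10 (0.661%) held 3 or more optimal summits, a comparison chosen after the data were seen.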

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

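The ce10 count and the shuffled-centre background for 6-mers were chosen after the data were seen, and the other alternatives before. The replicate overlap (40.3% to 81.3%), the promoter-proximal share (36.6% to 64.8%), the excess of signal at promoters (15.9 to 22.1 percentiles), the head-to-head odds ratio (2.35 to 5.83) and the autosome centre odds ratio (1.25 to 1.68) kept their direction and their side of the threshold under each alternative run. The number of optimal peaks was 5683 in ce10 and 5531 with overlapping peaks merged. Between 15 and 22 of the 30 gene lists, 7 or 8 of the non-coding classes and 1204 to 1629 of the 6-mers passed.

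The X share lost its call against chromosome length, where the odds ratio was 0.9654 (exact binomial p = 0.322) and not 0.693, because the other pooled regions lie on X more often than its length gives. With genes that have any pooled region as background, which leaves 7368 genes, the odds ratio of body wall muscle markers turned to 0.9609 and that of F-box and MATH-BTB genes to 1.0467. Lists that were not past the threshold, and did not pass it there, crossed an odds ratio of 1 as well. With that background these were Wnt (0.5829), TGF-beta and heterochronic (0.9075 each) and coelomocyte and excretory genes (0.7). Others were Wnt within 250 bp (0.6282), coelomocyte and excretory genes within 1000 bp (0.909), histones with the nearest 5′ end only (0.9727), and TGF-beta (0.3994) and coelomocyte and excretory genes (0.5707) in the 2846 strongest peaks. With each replicate alone the odds ratio was 0.8821 to 0.9096 for Wnt and 0.7696 to 1.2132 for coelomocyte and excretory genes, and antisense RNA genes had 0.9952 to 1.3725 times the shifted share. Against shuffled centres AAAATT turned to 1.0932, no longer past the threshold, and AAAAAT to 1.4248, and the split of 6-mers was 420 more and 784 less frequent, against 848 and 688 with flanks. That background holds the base composition of the centres themselves. Over the single lists and their alternatives, 171 values kept their call and direction, 14 lost the call with their direction kept, 11 gained it and 14 changed direction. Of these last, 2 (body wall muscle and F-box) also lost their call, so 16 calls were lost. Their cause was not tested beyond the ribosomal protein distances in the other observations. With each replicate alone, 22 lists passed without replicate 1 and 17 without replicate 2. The peaks of the named genes ranked within the 5692 highest of the single replicate in 183 cases and below them in 4, and 1 (syp-2) had no matching peak in replicate 2. Depth is unknown, so what was missed for want of reads cannot be judged.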

Other observations

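The tests in this part were chosen after the peak lists had been examined. The comparison among genes with any pooled region was set beforehand as an alternative, but its use as a test of ChIP-prone promoters was chosen after its values had been seen. The tests of sequence composition, summits without GAGAGA, neighbouring genes and 5′ ends without AG were chosen after related values had been seen.

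Peaks also stood at genes for the SL2 spliced leader RNA, which is joined to the 5′ ends of downstream messages of operons. Of 18 annotated sls-2 genes, 6 had a summit within 500 bp, with sls-2.1 (II:5844865-5844974) at rank 13, sls-2.4 (I:4172206-4172315) at rank 38 and sls-2.2 (II:5543598-5543707) at rank 68. The others were sls-2.8 (rank 910), sls-2.7 (rank 3314) and sls-2.6 (rank 4488). Of the 12 annotated genes of the other spliced leader family, sls-1, 0 had a summit within that distance. Reads that match several copies cannot be resolved from the peak lists, and no test was made of these counts. Places that enrich in any ChIP experiment could not be told apart here either. Of the 2805 optimal peaks away from coding 5′ ends, 800 (28.5%) lay within 500 bp of the 5′ end of a non-coding gene of any class. Shifted summits gave 12.9% (permutation p = 0.002, two-sided, the smallest that 1000 shifts can give), a 2.21-fold excess. Without piRNA genes and pseudogenes, the classes with fewer peaks, it was 683 (24.3%) against 7.15%, or 3.40-fold.

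The leading 6-mers differed in where they occurred. GAGAGA was in 36.4% of summit centres away from coding 5′ ends and 26.1% of those near them (odds ratio 0.618 for near against away, Fisher's exact p = 5.82e-17). GAGCGC had the opposite distribution, with 15.1% near coding 5′ ends and 5.24% away from them (odds ratio 3.23, Fisher's exact p = 4.20e-36). ACGCAG was in 17.8% near and 15.8% away (odds ratio 1.16, Fisher's exact p = 0.0365). In 4 equal groups of the optimal peaks, ACGCAG was in 23.7%, 18.2%, 13.98% and 11.4% of centres from the highest to the lowest signal, and GAGAGA in 33.5%, 32.0%, 30.4% and 28.9%. ACGCAG was in 24.3% of centres with GAGAGA and 13.4% of those without (odds ratio 2.08, Fisher's exact p = 2.66e-23), and 2300 centres (40.4%) had at least one of them. These p-values were not adjusted. GAGAGA and ACGCAG can overlap within a single stretch of sequence, and such cases were not left out of the counts. Their joint presence therefore need not mean separate elements.

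A first pattern was the frequency of peaks at the 10 lists of mainly housekeeping genes. Place on the chromosomes was argued against as the whole cause, since all 10 lists kept more peaks than other genes after stratifying by chromosome, middle part and head-to-head arrangement. Ribosomal proteins then had an odds ratio of 16.1 (7.78 to 33.5), against 29.3 without strata, so place may account for part of it. Odds ratios rose for pan-neuronal markers, body wall muscle markers and chromatin and synMuv genes, and fell for the other lists. GC content upstream of the genes was argued against in the same way, with 10 of 10 kept and ribosomal proteins at 28.3. Promoters that enrich in any ChIP experiment may account for part of it and stay open, since 8 of the 10 lists kept their call among genes with any pooled region and no ChIP of an untagged strain was analysed here. The number of annotated 5′ ends per gene was not adjusted for. The design has 1 group, so no biological explanation was tested.

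A second pattern, for which no biological explanation was tested, was the 848 6-mers more frequent in centres than in flanks. Base and dinucleotide composition of the centres may account for most of them, since 37.15% (315) stayed more frequent against shuffled centres and 125 became less frequent. Composition was argued against as the whole cause for the 12 leading 6-mers, since 12 stayed past the threshold. Their odds ratios fell to between 1.97 and 4.69 from between 3.59 and 10.6. Shuffled centres keep the dinucleotides of any element in them, and held GAGAGA in 15.1% of cases. So neither this fall nor the count of 6-mers above can tell how much is due to composition and how much to such an element. Reads piling up on GA simple repeats were argued against for the 5 leading 6-mers without GAGA or AGAG: at the 2089 summits with no GAGAGA in the 701 bp around them, ACGCAG had an odds ratio of 7.9292 (6.04 to 10.5) and the lowest of the other 4 was 5.023 (CGCAGA, 3.92 to 6.47). For the 7 with GAGA or AGAG they stay open, since leaving out the 290 summits with a GA run of 10 bp or more left odds ratios of 3.4153 to 7.84, but removing so few could not have brought any below 3.01 (nor ACGCAG, at 10.5156, below 7.28).

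The last pattern was the distance of ribosomal protein peaks, which lay a median of 280 bp upstream of the annotated 5′ end (65 genes, quartiles 252 and 352), against 168 bp for the other 3335 bound genes (permutation p = 1e-05, two-sided, the smallest that 100000 resamples can give, adjusted p = 3e-05). Peaks that belong to a neighbouring gene were argued against as the whole cause, since the difference stayed with each peak given to its nearest 5′ end only. The peaks of 42 ribosomal protein genes then lay at a median 112.5 bp farther than the others (permutation p = 5e-05). Those were 42 of the 65 (64.6%), while 2702 of the other 3335 genes kept a peak, so neighbouring genes may account for part of the distance. Annotated 5′ ends that are splice acceptors of trans-splicing may account for part of it. The acceptor motif TTCAG stood directly before the 5′ end of 55.4% of the ribosomal protein genes and 24.4% of the others (Fisher's exact p = 1.27e-07), and among genes with it the difference was 64 bp (permutation p = 0.00969), between the bounds of 50 bp and 100 bp set beforehand. Among genes without that motif the difference was 125 bp (275 against 150 bp, permutation p = 0.00038). That comparison cannot decide, since most of its ribosomal protein genes could still follow another acceptor. Only 6 of those 29 had a 5′ end that follows no AG, against 1851 of the 2522 others. Among genes whose 5′ end follows no AG the difference was 128 bp (permutation p = 0.0608), over those 6 ribosomal protein genes, so the explanation stays open.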
